A study of Bacillus subtilis with 9 samples.

How the data were processed

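Cells of the 3 strains were fixed with 1% formaldehyde for 30 min and chromatin was sheared by sonication, per the labels' protocols. ScpB was precipitated with an anti-ScpB antibody, DNA fragments of 220 to 250 bp were made into libraries with 15 PCR cycles, and reads of 150 bp were obtained, per the labels' protocols. The labels state 20 to 30 M reads per library.

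Reads were trimmed with Trimmomatic 0.39, aligned with Bowtie2 and handled with SAMtools, per the submitters' processing notes, and the versions of Bowtie2 and SAMtools are not given in the sources used here. The genome build, the window counting tool and any filter on reads are also not given in the sources used here. The 3 signal tables, per the file headers, list each library's value in 4216 adjoining windows of 1 kb made by the authors from sorted alignments. Every value of the deposited signal is a whole multiple of 1 step per library (100% within 0.05 of a whole number), and the step is taken as 1 read scaled to 1 M of that library's reads, so the signal is reads per window scaled to the library's own reads. A column sums to about 1.1 M, and why this exceeds 1 M is not given in the sources used here. The 3 ratio tables hold each window's ratio to a WT library as deposited by the authors, to WT repeat 1, WT repeat 2 or the WT input. They were recomputed from the signal, no window with a ratio was off at a relative tolerance of 0.0001, and all tests used the signal. Column names give the strain and repeat in a shortened form, and 2 strain numbers are spelled in 2 ways. All columns could be matched to a sample, and 0 were left over.

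Coordinates of the tables do not start at dnaA. The reference annotation ASM904v1, with 4536 genes, was used for names only. Its positions match those of the tables after a shift of 2136800 bp. The match was found by placing the 16S and 23S rRNA genes on the windows with the lowest input signal (r = 0.899 across windows, next best 0.351, and -0.00929 unshifted), and shifts from 2136720 to 2136880 bp fit as well to within 0.001. All 34 windows with no reads in the WT input hold an rRNA gene. Only positions of the deposited tables are printed, and the edges of a gene in them are uncertain by the width of that range. The annotation lists no gene scpB, and the neighbour of scpA is listed as spcB, so its window was added after the data were examined. No genome sequence was used here, so the planned result on parS sites, its alternatives and the list of parS windows were not run.

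Windows whose mean over the 6 ChIP libraries was under 0.1 of the median window, which is a value of 23.7, were left out of the tests, which kept 4177 windows and removed 39. The test was limma 3.58.1 in R 4.3.3 on log2(signal + 1), with all 3 ChIP groups in 1 fit, no block, moderated variances and Benjamini-Hochberg adjusted p under 0.05 over the windows, two-sided. Fold changes are on the log2(signal + 1) scale. On data simulated for the mutant against WT, with 200 of 4177 windows changed, the same steps recovered 62.5% of windows changed 1.2-fold, 93.5% changed 1.5-fold and 98.5% changed 2-fold, and 5.30%, 4.59% and 5.29% of the calls were false. The simulated windows were independent and few changed. In the real data most windows were called and adjoining windows moved together, so these rates need not hold there. ChIP repeats had a Pearson r of 0.996 in WT, 0.995 in the ParB mutant and 0.992 in ΔparB over windows on the log2 scale, and SDs of log2 differences of 0.109, 0.0881 and 0.0896. These exceed the sampling coefficient of variation of a median window, so no library was counted as a copy of its repeat.

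The origin and terminus regions are the windows within 100 kb of dnaA and of rtp. Their levels were compared by two-sided exact permutation tests over all splits of the libraries. Lists were tested with camera with an estimated correlation, Benjamini-Hochberg adjusted over 12 lists and 3 comparisons. A window belongs to a gene list if a listed gene covers at least 100 bp of it. The planned tRNA list was empty because no tRNA gene is that long, and a list of the windows that hold at least 50 bp of one was added after the data were examined. Tables were handled with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

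The windows named were fixed by rule before the data were examined: those of parB, smc, scpA and scpB, the peaks of the 10 regions with the highest WT signal, the extreme windows of the 10 regions with the largest change per comparison and direction among those that moved alike in both repeats, and the 3 windows of each list with the largest change. The windows beside dnaA, and all those of the origin region that were higher in ΔparB, were chosen after their values were seen. Alternatives fixed beforehand were a pseudocount of 10 or 0.1, no filter, division by the median window, the repeat number as a block, means over 5 windows, variances with a trend and robust, leaving out each library, origin regions of 50 and 200 kb, levels relative to the median window or over input, a preset correlation of 0.01, and fry. Division of each ChIP library by the input of its strain in the window and list tests, the lists under the other settings of the fit, changes against neighbouring windows, and the origin level without the library labelled ΔparB repeat 1 were added after the data were examined.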

Results

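The series measured where the condensin subunit ScpB sits on the chromosome of Bacillus subtilis, by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody against ScpB. ScpB belongs to Smc-ScpAB, the bacterial condensin that helps sister chromosomes to separate, and ParB is the partition protein that binds parS sites near the replication origin and recruits this complex. There were 3 strains, each with the kanR marker at the parB locus: a strain with wild-type ParB (WT), a strain with the ParB substitutions L69S, K70E and E101K (the ParB mutant), and a strain without parB (ΔparB). Each strain had 2 ScpB ChIP libraries, called repeat 1 and repeat 2 in the labels, and 1 input library, so that 9 libraries were compared over 4216 windows of 1 kb. Nothing in the labels says that the repeats came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

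Library size, read from the value that 1 read adds to a window, was 45.3 M (M for 1e6) and 40.2 M reads in the WT ChIP libraries, 40.4 M and 34.7 M in those of the ParB mutant and 27.5 M and 36.9 M in those of ΔparB. The input libraries held 51.6 M reads in WT, 39.8 M in the ParB mutant and 50.9 M in ΔparB. A median window held between 6655 and 13292 reads, for a sampling coefficient of variation between 0.867% and 1.23%. Reads were amplified over 15 PCR cycles, so this coefficient covers counting error only. The labels state 20 to 30 M reads per library, which all but the library labelled ΔparB repeat 1 exceed, and if both mates of a fragment were counted the counting error is larger than this. Values are the deposited signal per 1 kb window, scaled to each library's own reads, and a mean window held 261 in each library. A higher value is thus a larger share of a library's reads and need not be a larger amount of bound ScpB. Positions are those of the deposited tables, whose numbering starts near the terminus and places dnaA, beside the replication origin, in the window from 2137001 to 2138000 and rtp, in the terminus, in the window from 4154001 to 4155000. Windows are named by the annotated gene that covers most of them.

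The windows that hold parB were read first, because they check the strain labels. Most of parB lies in the window from 2127001 to 2128000, where input signal was 367 in WT, 522 in the ParB mutant and 181 in ΔparB. Relative to the windows around it, the ΔparB input stood there at 0.411 of the WT input. ChIP signal in this window was 1455 and 1692 in the WT libraries, 1502 and 1848 in the ParB mutant libraries and 698 in ΔparB repeat 2, but 2995 in the library labelled ΔparB repeat 1. In the window of sprC from 2126001, which holds the rest of parB, the values were 1363 and 1466 in WT, 1078 and 1145 in the ParB mutant, 801 in ΔparB repeat 2 and 1647 in the library labelled ΔparB repeat 1. The library labelled ΔparB repeat 1 therefore went against its label at parB, although its profile over all windows was closest to that of ΔparB repeat 2, with an SD of log2 differences of 0.0896 against at least 0.207 for any other ChIP library. Neither window passed the limma test in ΔparB against WT with all libraries, with log2 changes of -0.12 at parB and -0.30 at sprC. Without the library labelled ΔparB repeat 1 both were lower than in WT, with log2 changes of -1.17 at parB (limma adjusted p = 0.000615) and -0.82 at sprC (adjusted p = 0.000235). Without ΔparB repeat 2 both were higher than in WT, with 0.93 at parB (limma adjusted p = 0.00147) and 0.22 at sprC (adjusted p = 0.0279). Results for ΔparB below include that library unless it is said to be left out.

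In WT, ScpB signal was highest beside the replication origin and lowest in the terminus. The highest window, in the tRNA modification gene mnmE 3.71 kb left of the start of dnaA, held 4474 ± 202 (SD, n = 2), which is 17.1 times the mean window. The window of rnpA, which encodes the protein part of RNase P, held 4218 ± 205, and the window of dnaA, the replication initiator, held 3771 ± 82. The 43 windows in the top 1% fell into 10 regions, of which 5 lay within 100 kb of dnaA, and 41 of the 43 windows lay within 500 kb of it. Left of dnaA, the other regions peaked in ictI, yycS (2048 ± 58), fbp and bglA within 100 kb. Farther out on the same arm they peaked in ilvK (1700 ± 86), a branched-chain amino acid aminotransferase, in qoxB, a subunit of a quinol oxidase, and in the extracellular protease gene vpr (1512 ± 78). Right of dnaA they peaked in poxB (1711 ± 32) and, 1422 kb away, in mtnA (1209 ± 20). ChIP signal divided by input signal was 2.68 ± 0.052 over the 100 kb left of dnaA and 1.73 ± 0.024 over the 100 kb right of it. It was 0.580 ± 0.015 and 0.467 ± 0.027 in the windows more than 1500 kb away on the left and right arms. The 2 WT repeats had a Pearson r of 0.996 across windows on the log2 scale, where windows are not independent replicates.

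**Figure D1:**
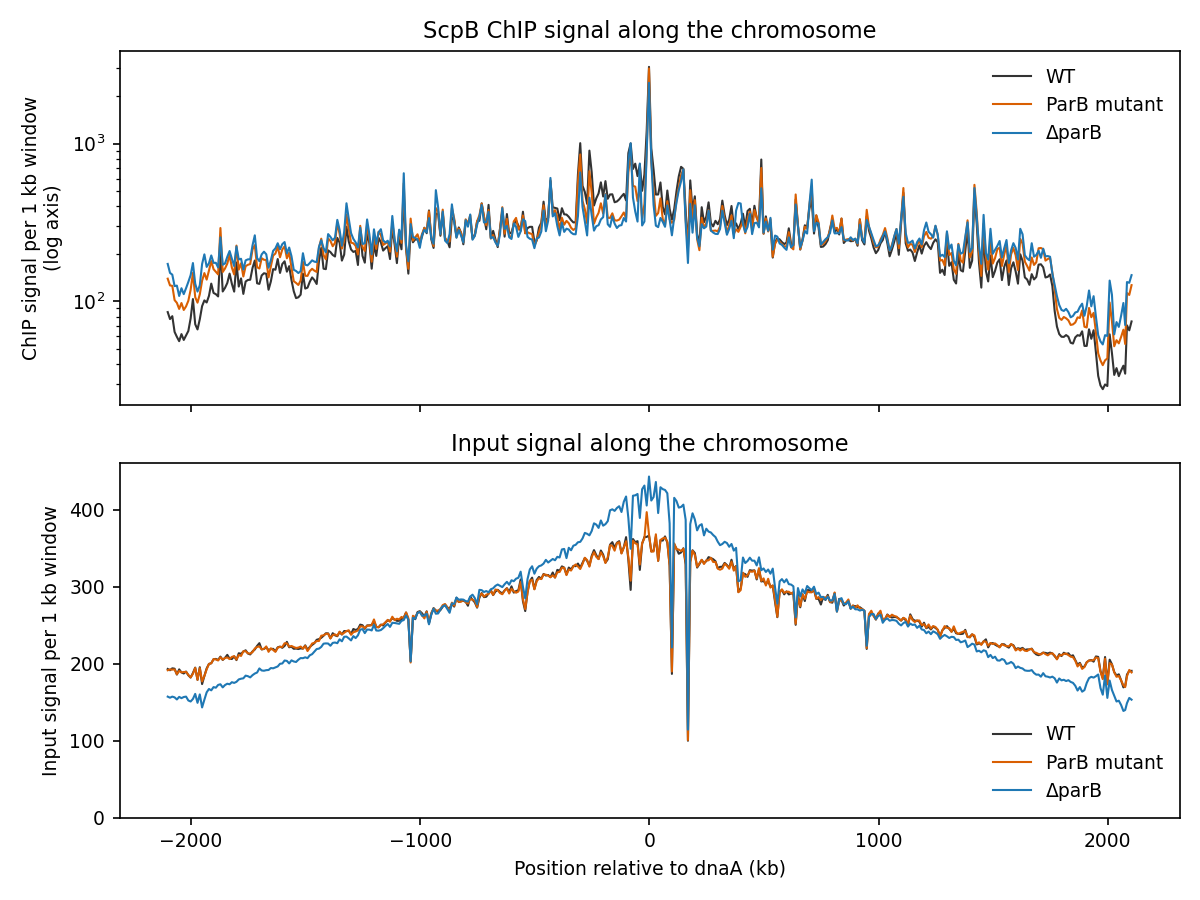
Mean ScpB ChIP signal of the 2 repeats (top, log axis) and signal of the 1 input library (bottom) per 1 kb window, averaged over 10 kb, against the position relative to dnaA in kb, for WT, the ParB mutant and ΔparB. The ChIP profiles peak at dnaA and are lowest in the terminus, where WT lies below both other strains, and the input profile of ΔparB is the steepest, with an origin to terminus ratio of 2.50 against 1.81 in WT.

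The comparison of the ParB mutant with WT asks how the 3 substitutions in ParB change the distribution of ScpB. ScpB signal was lower over much of the chromosome within 600 kb of dnaA and higher toward the terminus. At the peak beside dnaA no change passed: the mnmE window held 4517 ± 266 in the mutant against 4474 ± 202 in WT, and the dnaA window 3794 ± 44 against 3771 ± 82 (n = 2 each). The deepest loss was in yyaD, in the window from 2125001, where signal was 1109 ± 11 in WT and 420 ± 9.2 in the mutant, a log2 change of -1.40 (SE 0.042, limma adjusted p = 8.21e-06). This window adjoins the sprC window from 2126001, which holds part of the altered parB locus. ΔparB was lower than WT in the yyaD window too, at 575 and 561. Signal was also lower in ccpB (log2 change -0.68), in hutU and hutH of histidine degradation (both -0.56). It was lower, too, in yaaC (-0.53), in dltD of teichoic acid D-alanylation (-0.52), in trmNF (-0.48), in gyrA, a gyrase subunit (-0.45), in the ammonium transporter gene amtB (-0.37), in albA (-0.34) and in nocA, the nucleoid occlusion gene (-0.33). Among the highest WT regions, ilvK (-0.48), bglA (-0.53), ictI (-0.52), qoxB (-0.44), fbp (-0.32), vpr (-0.31), poxB (-0.26) and yycS (-0.24) were lower too.

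Most of the named gains in the ParB mutant were in windows below the mean window of 261 in WT. The window of dhaS, an aldehyde dehydrogenase gene in the terminus region, went from 62.2 ± 11 in WT to 120 ± 8.8 (log2 change 0.94, SE 0.11, limma adjusted p = 0.000329). The window of yoaV went from 27.0 ± 9.2 to 50.3 ± 3.2 (0.91) and ythA from 251 ± 0.18 to 430 ± 6.3 (0.78). Windows in the plipastatin synthetase genes ppsB (0.75) and ppsD (0.69), in yneJ (0.61), in the RNase Y gene rny (0.60), in spoIVFB (0.57) and in the polyketide synthase gene pksJ (0.56) were higher as well, though rny did not pass without mutant repeat 2 (0.54, adjusted p = 0.0557). In the smc gene, the windows from 3803001, 3805001 and 3806001 were higher by 0.47, 0.42 and 0.38, and that from 3804001 did not pass (0.40, adjusted p = 0.077), though it did without mutant repeat 1 (adjusted p = 0.0401) or either ΔparB library (0.0403). Without WT repeat 1 the windows from 3805001 and 3806001 no longer passed (adjusted p = 0.0657 and 0.0647), nor without mutant repeat 2 (0.105 and 0.098), and that from 3805001 did not pass with a trend in the variances either (0.102). The window of scpA, whose product pairs with ScpB, did not pass (0.45, adjusted p = 0.249), but passed when either ΔparB library was left out of the fit (adjusted p = 0.0103). The window of its neighbour, listed in the annotation as spcB, was higher by 0.46 (adjusted p = 0.00685). A rise does not set smc, scpA and spcB apart, since all lie more than 1500 kb from dnaA. There 576 of 608 windows on the right arm, which holds smc, and 602 of 608 on the left were higher. The median log2 change over the 10 kb that hold scpA and spcB was 0.33. The mtnA window was higher by 0.11 (adjusted p = 0.0351), a call that ended when each library was divided by its median window (0.03) or when any 1 of the 6 libraries was left out (adjusted p from 0.0568 to 0.146).

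By limma over 4177 windows, 2705 windows (64.8%) differed between the ParB mutant and WT at an adjusted p under 0.05, 1964 higher and 741 lower. Dividing each library by its median window gave 2512, of which 1411 were higher and 1101 lower, because that scaling brings the median log2 change of all windows from 0.11 to 0.02. Of the 43 highest WT windows, 26 were lower and 1 was higher. They were picked on the same WT libraries, which favours a fall, and 41 of them lie within 500 kb of dnaA. Adjoining windows joined to 119 higher regions, the largest with 665 windows that passed, and 74 lower regions, the largest with 105. More than 1500 kb from dnaA, 602 of 608 windows on the left arm and 576 of 608 on the right arm were higher, and none was lower, whereas 196 of 200 windows between 100 and 300 kb left of dnaA were lower.

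**Figure D2:**
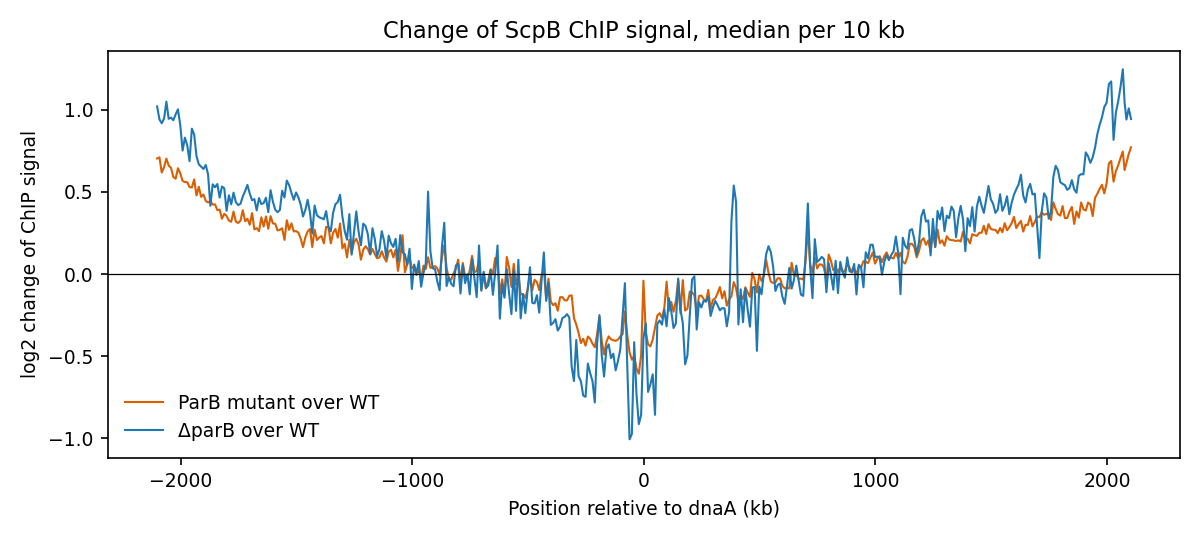
Median log2 change of ScpB ChIP signal against WT per 10 kb, for the ParB mutant and ΔparB, against the position relative to dnaA in kb. Both curves are mostly below 0 around dnaA and above 0 in the terminus, where the median window of the terminus region was higher by 0.61 in the mutant and 0.97 in ΔparB.

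In the region lists fixed before the data were examined, the origin region (100 kb each side of dnaA) had 160 of 186 tested windows lower in the ParB mutant and 0 higher (161 and 0 adjusted over the list alone). The median log2 change was -0.37, and limma's camera test gave an adjusted p of 0.067 with an estimated correlation. In the terminus region 187 of 197 windows were higher and 0 lower (191 and 0 adjusted over the list alone; camera adjusted p = 0.404). The prophage SPβ was higher in 91 of 91 windows, led by yorG (0.81) and yosV (0.79), with an adjusted p of 0.212. That count does not set SPβ apart. Its sunT window lies more than 1500 kb left of dnaA, where 602 of 608 windows were higher. The PBSX prophage was higher in 25 of 30 windows (28 adjusted over the list alone; adjusted p = 0.404) and the skin element in 19 of 20 (20 adjusted over the list alone; adjusted p = 0.404). Flagella and chemotaxis genes, such as fliI (0.45) and cheB (0.43), had 31 of 42 windows higher and 1 lower (adjusted p = 0.653). Glycolysis and pyruvate dehydrogenase genes had 11 of 19 windows higher, pdhD among them (0.33), and 2 lower (adjusted p = 0.744). Chaperone genes had 4 of 7 higher, 3 of them in dnaK and dnaJ, and 0 lower (adjusted p = 0.496). Of all 4177 tested windows 1964 were higher, mostly toward the terminus, so these counts cannot tell a gene list from its position. Against neighbours within 25 kb, 16 of 30 PBSX windows, 12 of 20 skin windows and 22 of 42 flagella windows stood above.

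Lists of highly transcribed genes were split in the ParB mutant. Ribosomal protein genes had 15 of 43 windows higher and 18 lower (adjusted p = 0.404), with a median log2 change of -0.05 and a mean of 0.02, so that median and mean differ in sign. Translation factors and RNA polymerase had 7 of 23 higher, among them tsf (0.39), and 12 lower (9 and 12 adjusted over the list alone; adjusted p = 0.256). ATP synthase genes had 3 of 8 higher, with atpC at 0.35, and 3 lower, with atpB at -0.24 (adjusted p = 0.72). The rRNA genes had 3 of 20 tested windows higher and 7 lower (adjusted p = 0.212). These values are uncertain, because only 20 of the 56 windows of that list were tested. Many rRNA windows held no reads: the 34 windows at 0 in the WT input all hold an rRNA gene. In rrnO the windows from 2147001 to 2150001 were at 0 in every ChIP library, which leaves the windows at its ends. None of the 36 tests of 12 lists in 3 comparisons passed with camera and an estimated correlation, and 7 had an unadjusted p under 0.05. With the preset correlation of 0.01, 25 of the 36 passed, and with fry, which tests whether a list moves 1 way on balance and does not compare it with other windows, 27 passed.

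The comparison of ΔparB with WT asks how ScpB is distributed without ParB. The peak beside dnaA was lower and moved toward dnaA: the mnmE window fell to 2870 ± 170 (log2 change -0.64, SE 0.063, limma adjusted p = 6.09e-05) and jag, oxaAA and rnpA changed by -0.55, -0.48 and -0.39. The dnaA window, at 3570 ± 165, and the dnaN window, at 2175 ± 35, did not pass (-0.08 and 0.02). These values are not divided by input, which was higher in ΔparB there, at 443 against 366 in WT over the 10 kb from 2130001. The deepest losses were at secondary WT peaks. Signal in vpr went from 1512 ± 78 to 479 ± 16 (log2 change -1.66, SE 0.052, adjusted p = 3.31e-06) and in ilvK from 1700 ± 86 to 616 ± 25 (-1.46). The windows of ccpB (-1.27), the cell wall sensor kinase gene walK (-1.12), dayD (-1.05), poxB (-1.05 in the window from 2627001), hutH (-0.94), bglA (-0.85), qoxB (-0.83), yycS (-0.80), ictI (-0.75), amtB (-0.72) and ybaR (-0.68) were lower too. In fbp (window from 2050001) signal was 985 ± 37 against 1075 ± 14, a change of -0.13 that passed with all libraries (adjusted p = 0.0307) but not without ΔparB repeat 2 (-0.09) or either WT library (-0.11 and -0.14). The change of mtnA (-0.10, adjusted p = 0.0452) did not pass when any 1 of the 6 libraries was left out. Divided by the input of each strain it was -0.02 (limma adjusted p = 0.582).

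The largest gains in ΔparB were in windows far from dnaA. The window of yobI went from 38.9 ± 4.6 in WT to 135 ± 11 (log2 change 1.77, SE 0.13, limma adjusted p = 1.37e-05). The window of ythA went from 251 ± 0.18 to 636 ± 0.31 (1.34), and sunT, the sublancin transporter gene of SPβ, from 142 ± 0.62 to 353 ± 24 (1.30). Gains of 0.96 in ysoA and 0.83 in ywmA also passed. The 4 smc windows were higher by 0.84, 0.91, 0.86 and 0.72 and the spcB window by 0.86. As in the mutant, a rise does not set these genes apart. Beyond 1500 kb from dnaA, 594 of 608 windows on the right arm, which holds smc, and 604 of 608 on the left were higher. The median log2 change over the 10 kb that hold scpA and spcB was 0.48. The scpA window was higher by 0.97 (adjusted p = 0.0244), a change that rests in part on the library labelled ΔparB repeat 1, at 381 against 167 in repeat 2, and that was 0.37 without it (adjusted p = 0.0349). It did not pass without WT repeat 1 (0.83, adjusted p = 0.0793), without the filter (adjusted p = 0.0637) or with a trend in the variances (adjusted p = 0.155). Within 100 kb left of dnaA, 11 windows in 3 clusters were higher in ΔparB: yydD (455 ± 87 to 1001 ± 164, log2 change 1.14, adjusted p = 0.00109) with the fbp window from 2051001 (0.33) and yydB (0.69) beside it, a cluster of liaM (0.22), liaL (0.94), liaK (0.90) and liaE (0.29), and a cluster of yybK, yybM and yybN. In yybK signal went from 509 ± 47 to 1040 ± 152 (1.02), and the changes were 0.90 in yybM and 0.59 in yybN. These gains are not divided by input. Over the 10 kb from 2040001, which hold liaM and liaE, input was 389 in ΔparB against 335 in WT.

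By limma, 3284 of 4177 windows (78.6%) differed between ΔparB and WT, 2280 higher and 1004 lower. Without the library labelled ΔparB repeat 1 the count was 3035, with 2142 higher and 893 lower. Dividing each library by its median window gave 3290, of which 1899 were higher and 1391 lower, because the median log2 change of all windows was then 0.06 in place of 0.18. Of the 43 highest WT windows, 33 were lower and 0 higher, with the same limits of choice and position as in the mutant. Beyond 1500 kb from dnaA, 604 of 608 windows on the left arm and 594 of 608 on the right arm were higher and none was lower.

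**Figure D3:**
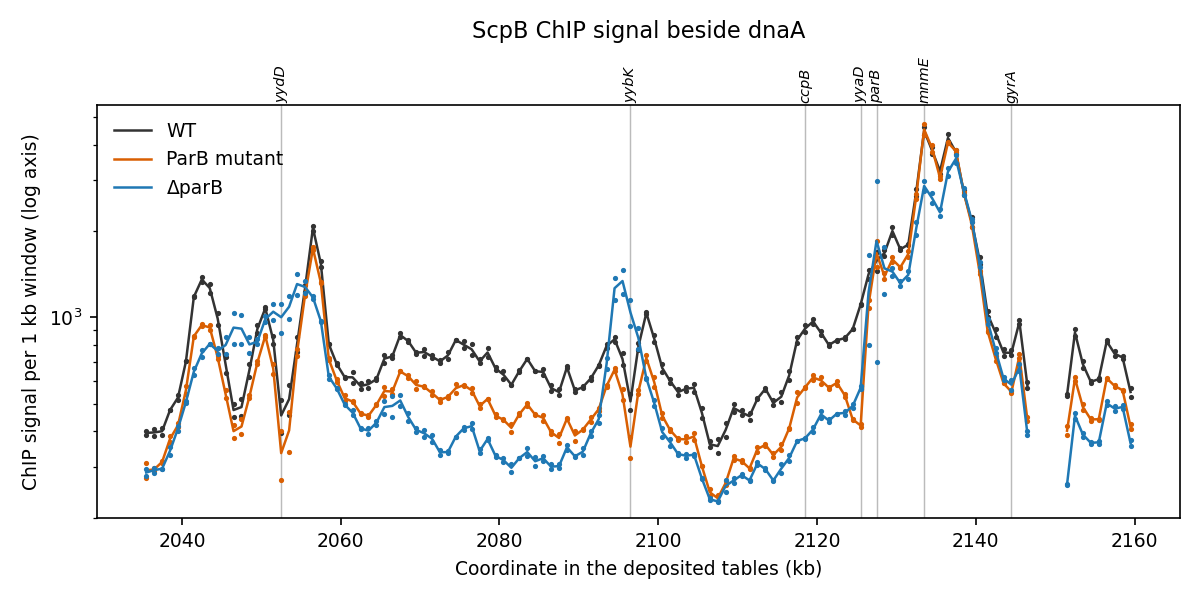
ScpB ChIP signal per 1 kb window (log axis) around dnaA for WT, the ParB mutant and ΔparB, against the coordinate in the deposited tables in kb, with lines for the mean of the 2 repeats, points for the repeats and vertical lines at named genes. Values under 200, most of them in rRNA genes, are not drawn. The mutant stands level with WT at mnmE and falls to 420 at yyaD, ΔparB lies above WT at yydD and yybK, and its repeats part at parB, at 2995 and 698.

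Of the lists, the origin region had 157 of 186 windows lower in ΔparB and 11 higher (157 and 11 adjusted over the list alone), with a median log2 change of -0.55 and a camera adjusted p of 0.067. The terminus region was higher in 197 of 197 windows (camera adjusted p = 0.404), SPβ in 91 of 91 (0.212), PBSX in 29 of 30 (0.404) and the skin element in 20 of 20 (0.401), each with 0 lower. As in the mutant, the SPβ count does not set it apart, since 604 of 608 left arm windows beyond 1500 kb were higher. The other counts cannot tell a gene list from its position either, since 2280 of all 4177 windows were higher, mostly toward the terminus. Against neighbours within 25 kb, 17 of 30 PBSX windows and 15 of 20 skin windows stood above. The rRNA genes had 15 of 20 windows lower and 1 higher (adjusted p = 0.0778), with the window from 2151001, at the end of the 23S gene of rrnO, at -1.03. They stay uncertain, since the other windows of that gene, from 2148001 to 2150001, held no ChIP reads. Ribosomal protein genes had 16 of 43 windows higher and 21 lower (22 adjusted over the list alone; adjusted p = 0.404), with the window of rplI at -1.04. Translation factors and RNA polymerase had 9 of 23 higher and 11 lower (adjusted p = 0.293), with infB at 0.50 in the window from 3871001. ATP synthase genes had 3 of 8 higher, with atpC at 0.63, and 4 lower, with atpB at -0.60 (adjusted p = 0.72). Chaperone genes had 4 of 7 higher, with dnaJ at 0.39, and 1 lower (adjusted p = 0.744). Glycolysis genes had 10 of 19 higher and 5 lower, with fbaA at -0.55 (adjusted p = 0.927). Flagella and chemotaxis genes had 23 of 42 higher and 10 lower, with sigD at 0.47 (adjusted p = 0.958). Without the library labelled ΔparB repeat 1 the windows that passed numbered 157 lower and 10 higher in the origin region, 14 lower and 1 higher in the rRNA genes, 15 higher and 18 lower in the ribosomal protein genes and 8 higher and 11 lower in the translation list. All windows of the terminus region, SPβ and skin stayed higher then. For glycolysis and flagella the median change was above 0 (0.17 and 0.22) while camera, which compares with all windows, gave the direction down.

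The direct comparison of the ParB mutant with ΔparB, fitted in the same model, asks where ScpB differs between the altered and the missing ParB. Signal in the mutant was higher at most of the WT peaks: in vpr it was 1215 ± 30 against 479 ± 16 (log2 change 1.34, SE 0.052, limma adjusted p = 4.26e-05). In ilvK it was 1222 ± 58 against 616 ± 25 (0.99) and in mnmE 4517 ± 266 against 2870 ± 170 (0.65). The windows of poxB (0.74 in the window from 2627001), dayD (0.73), walK (0.64 in the window from 2073001) and the DNA repair gene exoA (0.60) were higher as well, and so were those of the 23S genes of rrnA (0.72), rrnO (0.62) and rrnE (0.60). Signal in the mutant was lower in yydD (336 ± 91 against 1001 ± 164, log2 change -1.59), yybK (-1.55), yobI (-0.93), ynzK (-0.93), yoxD (-0.90), ppsA (-0.79), srfAA of surfactin synthesis (-0.72), the teichoic acid gene ggaA (-0.72) and sunS (-0.69). The yyaD window was lower in the mutant by 0.44 on the log2 scale (-0.44, adjusted p = 0.000632).

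By limma, 1661 of 4177 windows (39.8%) differed between the ParB mutant and ΔparB, 586 higher and 1075 lower in the mutant, or 691 and 827 with each library divided by its median window. This count rests on single libraries: it was 848 without the library labelled ΔparB repeat 1, 642 without ΔparB repeat 2, 667 without mutant repeat 1 and 1226 without mutant repeat 2, and it was 2859 when each ChIP library was divided by the input of its strain. Of the lists, the origin region had 103 of 186 windows higher and 17 lower (108 and 18 adjusted over the list alone; camera adjusted p = 0.0778) and the rRNA genes 13 of 20 higher and 0 lower (15 adjusted over the list alone; 0.067). The terminus region had 139 of 197 windows lower and 0 higher (162 adjusted over the list alone; adjusted p = 0.404), SPβ 80 of 91 lower (88 adjusted over the list alone; 0.212), skin 20 of 20 (0.293) and PBSX 12 of 30 (0.404). Without the library labelled ΔparB repeat 1, the windows that passed numbered 76 higher and 13 lower in the origin region, 75 in the terminus region, 57 in SPβ, 13 in skin, 6 in PBSX and 8 in the rRNA genes.

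Of the other lists in the ParB mutant against ΔparB, flagella and chemotaxis genes had 17 of 42 windows higher and 1 lower (camera adjusted p = 0.404), but 13 higher and 11 lower when ChIP was divided by input. Ribosomal protein genes had 14 of 43 higher and 5 lower (15 and 5 adjusted over the list alone; adjusted p = 0.404), glycolysis genes 4 of 19 higher and 3 lower (0.496). Translation factors and RNA polymerase had 3 of 23 higher and 3 lower (3 and 2 adjusted over the list alone; 0.426) and ATP synthase genes 3 of 8 higher and 3 lower (0.754). Chaperone genes had 0 of 7 windows past the limma threshold in either direction (0.744). For glycolysis the median log2 change was -0.04 and the mean 0.03, for translation factors the median was 0.01 and the mean -0.00487, and for chaperones both were below 0 (-0.00275 and -0.00647) while camera gave the direction up.

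Over the whole origin region, mean ScpB signal relative to the mean window was 2.77 ± 0.048 in WT, 2.24 ± 0.014 in the ParB mutant and 2.06 ± 0.11 in ΔparB (SD, n = 2 each). The mutant stood at 0.810 of WT, ΔparB at 0.747 of WT and the mutant at 1.09 times ΔparB. All of the mutant and ΔparB libraries lay below both WT libraries. A two-sided exact permutation test of 2 against 2 libraries gave p = 0.333 for each of the 3 comparisons, the smallest p this design allows. Over the terminus region the values were 0.183 ± 0.020 in WT, 0.280 ± 0.014 in the mutant and 0.358 ± 0.0074 in ΔparB, which is 1.53 and 1.96 times WT and 0.782 for the mutant over ΔparB, each again with an exact p of 0.333.

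**Figure D4:**
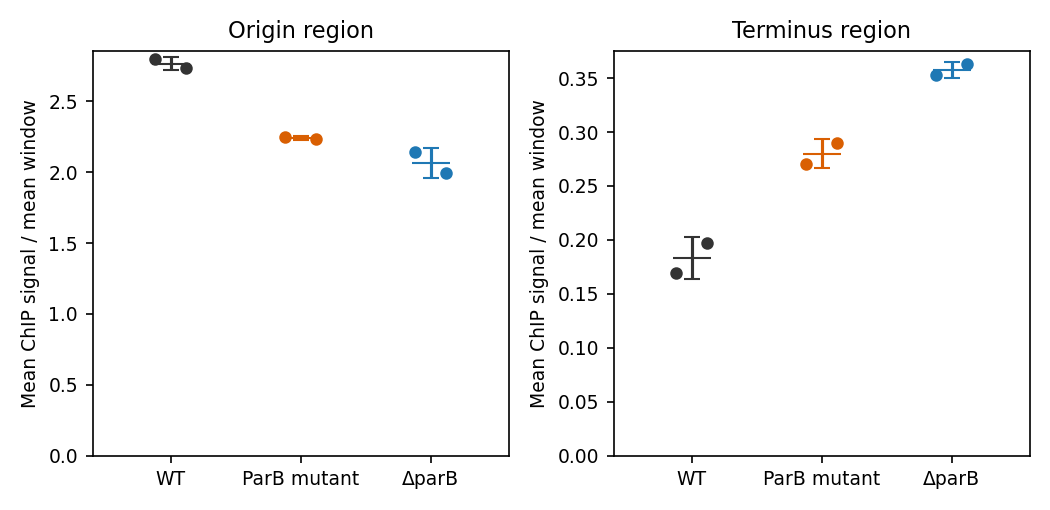
Mean ScpB ChIP signal divided by the mean window of the same library in the origin region (left) and the terminus region (right), 100 kb each side of dnaA and rtp, for WT, the ParB mutant and ΔparB. Points are the 2 repeats, bars the mean and error bars the SD: the order from high to low is WT, mutant, ΔparB in the origin region (2.77, 2.24 and 2.06) and the reverse in the terminus region (0.183, 0.280 and 0.358).

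Input libraries, the background measured without immunoprecipitation, had an origin to terminus ratio of 1.81 in WT, 1.83 in the ParB mutant and 2.50 in ΔparB, with 1 library per strain and so no error. The same ratio in ChIP libraries was 16.4 ± 2.0 in WT, 8.67 ± 0.48 in the mutant and 6.24 ± 0.45 in ΔparB. Divided by the input of each strain and relative to the median window, ScpB enrichment in the origin region was 2.66 ± 0.059 in WT, 2.04 ± 0.017 in the mutant and 1.63 ± 0.14 in ΔparB. In the terminus region it was 0.292 ± 0.030, 0.431 ± 0.021 and 0.632 ± 0.0050. In the same order of strains it was 2.61, 2.32 and 1.61 in rRNA genes, 2.06, 1.89 and 1.55 in ribosomal protein genes, 2.35, 2.22 and 2.02 in ATP synthase genes and 1.74, 1.58 and 1.42 in genes of translation factors and RNA polymerase. Glycolysis genes were at 1.46, 1.46 and 1.40, chaperone genes at 1.06, 1.13 and 1.14, and flagella genes at 1.02, 1.13 and 1.1. SPβ was at 0.442, 0.640 and 0.919, PBSX at 0.728, 0.801 and 0.889 and skin at 0.565, 0.657 and 0.821.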

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

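The tests of the excess at parB and scpA were all chosen after the excess was seen, and input libraries were searched window by window after the data were examined.

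The ParB mutant input, which enters the tests between strains only where ChIP was divided by input, stood above the WT input in 6 windows, relative to the windows around each, by more than 0.2 on the log2 scale. The spread of this local ratio over 4118 windows was an SD of 0.031, and 0 windows lay as far below. The ratio was 1.42 in the parB window from 2127001 and 1.42 in the sprC window from 2126001, which holds the rest of parB. It was 1.34 and 1.39 in the yydD windows from 2052001 and 2053001, 1.23 in yybK and 1.18 in comP, a sensor kinase gene of competence. In yydD, yybK and comP the WT input itself was low, at 0.400, 0.403, 0.523 and 0.599 of its neighbours. With 1 input library per strain these differences have no replicate check, and no explanation was tested.

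The library labelled ΔparB repeat 1 exceeded repeat 2 by 4.29-fold at parB, 2.27-fold at scpA and 2.05-fold at sprC, or 23.5, 13.2 and 11.6 times the SD between these repeats. The rest of its profile argues against a mislabelled library, since its distance to the nearest WT or mutant ChIP library was 2.32 times that to ΔparB repeat 2. Cells with parB mixed into the culture would bring parB to the WT level at most, and the library stood at 1.9 times the WT mean there. Outside DNA with genes of ParB and the condensin, such as plasmid or amplified DNA, may explain the excess and stays open. Of the windows with the highest ratio of repeat 1 to repeat 2, 5 of 10 held or adjoined such a gene. However, 3 of these are the parB locus and 2 the scpA locus, and the smc windows from 3804001 and 3805001 went the other way by 0.48 and 0.36 (-0.48 and -0.36). The rule written for that count took 4 as enough, so by that rule alone outside DNA would fit, and the condition on smc that left it open was added after the count was seen. The other windows among the 10 include lctE and amyE (log2 differences of 0.58, 0.57 and 0.52), and no biological explanation was tested.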

How the results depend on the processing

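Dividing by input in the window and list tests, the lists under other settings of the fit, and the origin level without the library labelled ΔparB repeat 1 were chosen after the data were examined. Counts of changed windows stayed within 1.5 times the reported ones with both pseudocounts, no filter, division by the median window, and variances with a trend. Means over 5 windows gave 645, 722 and 480 of 843 because fewer windows were tested. Leaving out 1 library gave 2109 to 2584 windows for the ParB mutant against WT, 2998 to 3247 for ΔparB against WT and 642 to 1852 for the mutant against ΔparB, each with the lone library assumed to vary like the others. Over input the last count was 2859. Both repeats of a strain were then divided by the same input library, so any input difference or error enters as a strain difference without added spread. How much of the rise this explains was not tested.

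With the repeat number as a block the counts were 2889, 3394 and 2095, 0 lists passed, and mean ratios within repeats in the origin region were 0.810, 0.746 and 1.09. Repeat differences of strain pairs correlated at 0.391, 0.221 and 0.205, but there are only 2 numbers, and the labels do not say that a number, or the name prefix that goes with it, marks a batch. The smc window from 3804001 in the mutant against WT passed with the block (adjusted p = 0.000378). With 1 choice changed at a time, origin ratios kept their direction, from 0.762 to 0.818, 0.626 to 0.756 and 1.08 to 1.24. Single repeats gave 0.804 to 0.817, 0.729 to 0.764 and 1.05 to 1.12, and combined choices with both repeats reached 0.591 and 1.30 in the last pair of comparisons. Without the library labelled ΔparB repeat 1, the ΔparB origin level was 1.99, against means of 2.77 in WT and 2.24 in the mutant. Of 36 list tests, 25 passed with the preset correlation and 27 with fry, 0 with any other setting; the preset correlation assumes less correlation between windows than most estimates here, and the cause was not tested for fry. Relative to the mean window, enrichment in the origin region was 2.41 in WT and 1.88 in the mutant, and in the terminus region 0.397 in the mutant and 0.584 in ΔparB, because the mean window lies above the median. Input origin to terminus ratios with 50 and 200 kb were 1.87 and 1.78 in WT, 1.91 and 1.79 in the mutant and 2.61 and 2.46 in ΔparB, because other windows enter. The ChIP ratios moved more, to 26.2 and 11.6 in WT, 13.7 and 6.38 in the mutant and 8.93 and 4.75 in ΔparB.

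Of 107 results for named windows, 1 reversed, fbp (window from 2050001) in the mutant against ΔparB, at 0.0289 over input. Division raises this value, since input over the 10 kb from 2050001 averaged 308 in the mutant and 349 in ΔparB. Settings other than leaving out a library gave 726 values with the same side of the threshold, 11 that no longer passed, 5 that newly passed in the same direction and 5 sign changes of values that had not passed before. Leaving out a library gave 580, 37, 16 and 9, and some of the 9, at parB and sprC, passed after the sign change. The WT repeats differed most in windows of the terminus with low signal, by up to 1.77-fold in ppsD, and the cause was not tested. Counting error in a median window, at most 1.23%, lay below the spread between repeats. The parS alternatives were not run because no genome was used here.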

Other observations

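The test of windows with poorly recovered input against the bounds of 0.05 and 0.1 was chosen before its result was seen, and all other tests, its comparison with the 11 windows included, and local comparisons here were chosen after.

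Against neighbours within 25 kb, the rRNA windows had a median log2 difference of 0.10 in the ParB mutant over WT (16 of 20 above their neighbours) and of -0.09 in ΔparB over WT (13 of 20 below). They stood 0.19 higher in the mutant than in ΔparB (17 of 20 above). These values are uncertain, since many rRNA windows held no reads and only 20 could be compared. Flagella and chemotaxis windows had a median of -0.11 in ΔparB over WT, with 36 of 42 below their neighbours, but of 0.01 in the mutant over WT. Windows that hold tRNA genes had 8 of 19 higher and 4 lower in the mutant, with yoeC at 0.74 and purA at -0.47 (limma camera adjusted p = 0.931), and 5 higher and 6 lower in ΔparB (limma camera adjusted p = 0.821). In the mutant against ΔparB 8 were higher and 1 lower (limma camera adjusted p = 0.675). None of these local medians was tested, and rRNA and flagella genes are named because each had the median farthest from 0 of all lists in at least 1 comparison. Those of ATP synthase genes were -0.016 and -0.00524 and those of ribosomal protein genes 0.0214 and 0.0144 in the mutant and ΔparB over WT. In the same order those of SPβ were 0.000285 and 0.00618, of PBSX 0.00322 and 0.0055 and of skin 0.00966 and 0.0491. Neighbours of such a window include windows of the same element, so these values cannot tell an effect of the element from position.

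In 11 windows of the origin region ScpB rose in ΔparB, by a median of 1.2 on the log2 scale against their neighbours, while the mutant changed there by 0.03. The change in input DNA was 0.0365 times that in ChIP, which argues against a copy number change of these windows. Input in them was at a median of 0.765 of the neighbours, and 17 windows elsewhere with lower input (median 0.599) changed by a median of only 0.0732 (SD 0.14, 13 above their neighbours), 7.98 SD below the 11. The 11 windows were picked for their rise in ΔparB, so part of this gap may come from that choice. With that limit, the gap argues against better recovery of poorly recovered DNA as the whole cause. A small part stays open, since 0.0732 lies between the bounds of 0.05 and 0.1 set beforehand. Some of the 11 windows also varied between libraries, which this test does not cover. In the yydD window from 2052001 repeats 1 and 2 held 516 and 394 in WT and 1117 and 884 in ΔparB. In the mutant they held 400 and 272, and mutant input in that window stood locally at 1.34 of WT input. No biological explanation was tested.

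In both strains scaled ScpB signal was lower in the origin region and higher in the terminus region than in WT. A single scaling factor per library cannot alter the origin to terminus ratio. On the log2 scale that ratio changed by -0.92 in the mutant and -1.39 in ΔparB. The ratio does not tell which end moved. Signal is scaled to each library's own reads, so a loss at the origin alone would also raise the terminus values. It would, however, raise all windows outside the origin by the same factor. ChIP over input 600 to 1000 kb left and right of dnaA stood at 1.02 and 1.03 of WT in the mutant and at 1.00 and 1.00 in ΔparB. Beyond 1500 kb it stood at 1.32 and 1.30 in the mutant and at 1.72 and 1.69 in ΔparB. These values argue against a loss at the origin alone in both strains. The input ratio was 1.01 times that of WT in the mutant, about level, and 1.38 times in ΔparB, the other way. Neither is the fall that DNA copy number would need, with 1 input library per strain. To test mixing, the WT profile was multiplied by each strain's input over the WT input, and input-like DNA of the strain was mixed into it. In ΔparB, with its steeper input, the first step steepens the profile. Mixing into the unscaled WT profile was not tested. A share of 17.8% in the mutant and 43.7% in ΔparB would then give the terminus levels. Yet 130 of 185 origin windows in the mutant (70.3%, 95% bootstrap interval 58.8 to 80.3) and 161 in ΔparB (87.0%, 78.1 to 94.0) missed the predicted change by more than 3 SD between repeat means. This argues against mixing in this form as the whole cause in both strains, while a part stays open. Over the 43 highest WT windows alone the median absolute gap was 0.209 in the mutant (0.0767 to 0.258, an interval added after the gap was seen). It was 0.378 in ΔparB (0.263 to 0.701), against a bound of 0.2. A biological difference between the strains stays open and untested.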
